A study of Mus musculus with 6 samples.

How the data were processed

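The samples were 6 polyA RNA-seq libraries, 3 from control and 3 from double-knockout mice, each from scraped small intestinal epithelium of 1 mouse. Per the labels' protocols the libraries were paired-end and made with a TruSeq RNA kit. Groups and animal numbers came from the sample titles, and the animal numbers are not shared between the groups, so nothing was paired or blocked.

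The count table the authors deposited holds whole-number counts per gene, not normalized. Per the submitters' processing notes, the tools were bcl2fastq, fastp 0.21.0, STAR 2.7.9a, featureCounts of Subread 1.6.2, FastQC 0.11.7 and DESeq2 1.23.10, with genome build mm10. The annotation, the strand setting and the filters are not given in the sources used here, so reads of a gene and an overlapping antisense gene cannot be told apart. A second table the authors deposited holds variance-stabilised values on a log2 scale; checked against the counts, each value was a rising function of the count over a median-of-ratios size factor. It was used for 1 alternative only. Of 55450 gene identifiers, 55104 matched a symbol, and the unmatched ones took up to 0.0421% of a library's counts. No identifier lay on the mitochondrial chromosome, so mitochondrial transcripts were not analysed here. Exon lengths, GC content and coordinates came from GENCODE M21 on mm10.

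Total counts ran from 23476031 to 46835165 per library. A floor of 3 counts corresponded to between 0.0586 and 0.173 CPM, and intervals and floors cover counting error only. Libraries of one genotype differed by far more than sampling noise (chi-square per degree of freedom of 63.8 or more in every pair), so none was counted as a duplicate. Correlations of log2 CPM were 0.966 to 0.975 within a genotype and 0.861 to 0.922 between genotypes.

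Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with its defaults left 15028 genes, libraries were scaled with TMM, and the quasi-likelihood test (robust) compared knockout with control, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change is its size over the square root of F. TMM factors were 1.28, 1.13 and 1.09 for controls 482, 483 and 486 and 0.975, 0.871 and 0.741 for knockouts 423, 476 and 477. The 20 most abundant genes took 12.8% to 15.9% of the counts in controls and 22.3% to 29.1% in knockouts. CPM are TMM-scaled, and log2 CPM used a prior count of 2. Gene lists (48, fixed before the data were examined) were tested with camera in limma 3.58.1 at a preset correlation of 0.01 where at least 3 members were tested, with the estimated correlation and fry beside it. Where a group had no count, folds are bounds against 3 counts over the group, and with 1 to 3 counts they are ratios with a 95% exact binomial counting interval.

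The genes named were set before the data were examined: both targets, every tested member of the carbohydrate list, the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 2 CPM and no overlap between genotypes, and up to 4 members with the smallest adjusted p of each other list. Predicted genes, unnamed identifiers and immunoglobulin or T cell receptor segments were left out of the ranking. Some genes named by this rule, one of the targets among them, are not reported here. Symbol families in the closing section were chosen after the data were seen.

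On simulated counts with the real means and library sizes (14627 genes, 200 of them changed), the test recovered 4% of genes changed 1.5-fold, 18% at 2-fold, 92% at 4-fold and 100% at 8-fold, and 8 of 115 calls were false. That simulation held no trend with gene length and a far smaller share of changed genes than the 5348 of 15028 called in the data. Its recovery percentages therefore do not give the test's power on these data. With a simulated trend (Spearman rho of -0.77 between log2 fold change and length, steeper than the -0.37 of the data) 1421 of 1547 calls were false without a correction and 9 of 123 with the length and GC correction, and the test as set beforehand makes no such correction.

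Alternatives set beforehand were 3 other scalings, 2 other filters, DESeq2 1.42.0, limma-voom with and without sample weights, limma-trend on the variance-stabilised values, the 20 most abundant genes left out, a test against a 1.5-fold change, and each library left out in turn. Removal of each library's smooth trend with exon length and GC content, or length alone, was chosen after the data were seen. The 10 splits of the 6 libraries into 3 and 3 were each refitted.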

Results

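The data were polyA RNA-seq counts per gene from small intestinal epithelium of adult mice, 1 library per mouse. The 3 control mice carried floxed alleles of both targeted genes without Cre, and the 3 double-knockout mice carried the same alleles with Vil1-Cre-ERT2, a villin-driven Cre recombinase that tamoxifen activates in the intestinal epithelium. NCoR1 (gene Ncor1) is a corepressor that recruits histone deacetylase activity to unliganded nuclear receptors. The epithelium was scraped off with a glass slide, and the labels do not say which section of the small intestine each library came from. The libraries are named here by genotype and animal number. The total counts were 37005552, 26199718 and 46835165 for controls 482, 483 and 486, and 28364787, 34568205 and 23476031 for knockouts 423, 476 and 477.

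The targeted gene Ncor1 was lower in every knockout library than in every control library. Ncor1 (ENSMUSG00000018501, mm10 chromosome 11, 62316426 to 62458541) stood at 140, 137 and 99.3 CPM in controls 482, 483 and 486 and at 31.3, 36.4 and 22.5 CPM in knockouts 423, 476 and 477. Its log2 fold change was -2.06 with an SE of 0.25 and an adjusted p of 0.00045. Ncor1 is a long gene (12811 exon bases), and after each library's trend with length and GC content was removed the log2 fold change was -1.60. All these values come from counts over the whole gene, and the labels do not give the floxed exons. The list of corepressor complex members had 2 that rose and 6 that fell of 15 tested, the deleted genes included (both counts the same when adjusted over the list alone). Of these, 2 fell without control 482 or knockout 477 and 3 without control 483 or knockout 423. Tbl1xr1, which encodes a subunit of the NCoR1 complex, rose by a log2 fold change of 1.17 (SE 0.19).

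The comparison of knockout with control asked which epithelial genes change in the double knockout. Only the knockout mice carried Vil1-Cre-ERT2, so effects of the deletion and of the transgene itself cannot be told apart. Of 15028 genes tested, 2596 rose and 2752 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 1935 and 1990 of them by more than 2-fold. With library-size scaling alone, which moves the median of all genes by -0.44, 1133 rose and 4554 fell, and 3299, 3545 and 3396 genes passed without control 482, control 483 or knockout 477. The libraries of the genotypes did not overlap in 7556 genes (50.3%), where chance gives 10%. Among the 12 highest changes Scd1, a stearoyl-CoA desaturase, went from 17.3 ± 3.93 to 14873 ± 3599 CPM (SD, n = 3; log2 fold change 9.75). Its paralog Scd3 had no count in any control library and was at least 186-fold higher against a floor of 3 counts over the control group. Whether reads of the abundant Scd1 were counted under Scd3 in the knockouts was not tested. Acot1 (log2 fold change 8.60) and Acot3 (5.93), acyl-CoA thioesterases, the carbonyl and aldo-keto reductases Cbr3 (8.54) and Akr1b8 (7.90), the transporter gene Slc16a9 (5.99) and Anxa10 (5.81) were also among the 12 highest. So was Esr1, the oestrogen receptor gene, at 0.0313 ± 0.00924 and 13.9 ± 3.58 CPM (SD, n = 3). The Cre-ERT2 transgene of the knockout mice contains a mutated oestrogen receptor ligand-binding domain, so counts under Esr1 are uncertain as a measure of the endogenous gene.

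The 12 lowest included Pla2g4c, a phospholipase A2 gene, and the gasdermin C genes Gsdmc2, Gsdmc3 and Gsdmc4, whose control levels differed between mice. Gsdmc4 stood at 334, 19.8 and 260 CPM in controls 482, 483 and 486 and at 1.74, 0.0665 and 0.460 CPM in knockouts 423, 476 and 477. The call of Pla2g4c (adjusted p = 0.0077) was lost without control 482 (adjusted p = 0.058) and that of Gsdmc3 (adjusted p = 0.0069) without knockout 477 (adjusted p = 0.061). The gasdermin C genes are near-identical neighbours, so the share of reads given to each is uncertain. The pseudogene Apol10c-ps had no count in any knockout library and was at least 125-fold lower against the floor of 3 counts over the group. The potassium channel gene Kcnj13 and the mucosal pentraxin gene Mptx1 each had 1 count over the knockout group, 461-fold (95% counting interval 82.5 to 18225) and 766-fold (137 to 30274) lower. Slc5a8, a sodium-coupled monocarboxylate transporter, had a log2 fold change of -7.53, Lrrc3 one of -6.76 and Sucnr1, the succinate receptor, one of -6.72.

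Carbohydrate digestion and transport genes fell in the knockout. Of 15 members tested, 11 fell, none rose and 4 did not pass the test, with the same counts when adjusted over the list alone. The series title names this theme, so the list is not independent evidence of its direction. The apical glucose carrier SGLT1 (Slc5a1, ENSMUSG00000011034, chromosome 5, 33104219 to 33162870) went from 5633 ± 360 to 1446 ± 90.8 CPM (SD, n = 3), a log2 fold change of -1.96 (SE 0.24, adjusted p = 0.00053). The basolateral carrier GLUT2 (Slc2a2, ENSMUSG00000027690, chromosome 3, 28697903 to 28731359) went from 607 ± 144 to 92.8 ± 12.3 CPM, a log2 fold change of -2.71 (SE 0.26). The fructose carrier GLUT5 (Slc2a5, ENSMUSG00000028976, chromosome 4, 150119283 to 150144169) went from 311 ± 31.7 to 116 ± 16.8 CPM, a log2 fold change of -1.42 (SE 0.21). The other carriers that fell were Slc2a7 (-2.93), Slc2a9 (-1.33), Slc5a4a (-2.17), Slc5a9 (-1.86) and Slc5a11 (-3.94). Among the brush border disaccharidases, lactase (Lct, -5.18), maltase-glucoamylase (Mgam, -2.01) and trehalase (Treh, -1.30) fell, whereas sucrase-isomaltase (Sis) stood at 5118 ± 803 and 4557 ± 904 CPM (SD, n = 3; adjusted p = 0.65). Slc5a4b (log2 fold change -0.12), Slc2a1 (0.22) and Slc2a8 (-0.38) did not pass the test either. With library-size scaling alone Sis and Slc5a4b also fell (-0.63 and -0.57), and Slc2a1 changed sign to -0.18. The list test gave an adjusted p of 6.7e-06 (camera, preset correlation), and an adjusted p of 0.34 with an estimated correlation.

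**Figure D1:**
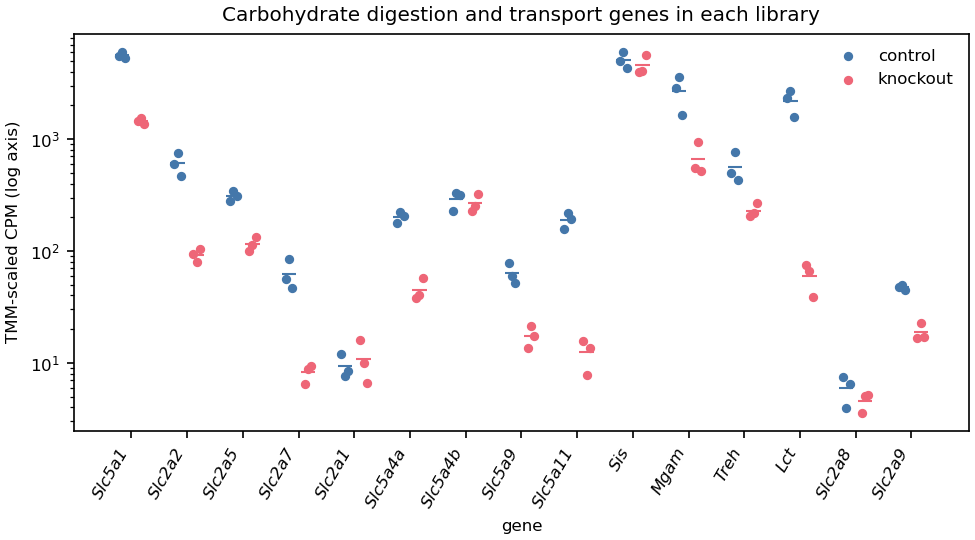
TMM-scaled CPM on a log axis for the 15 tested carbohydrate digestion and transport genes; points are libraries (3 control, 3 knockout) and short lines are group means. Slc5a1 stands between 5333 and 6032 CPM in the controls and between 1351 and 1532 CPM in the knockouts, whereas the Sis libraries of the genotypes overlap.

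Of 33 tested genes of fatty acid oxidation and PPAR targets, 26 rose and none fell; adjusted over the list alone, 27 rose and 1 fell. Besides Acot1 they included Acot2 (log2 fold change 5.12), the lipid droplet coat gene Plin2 (4.19) and the receptor gene Ppara (2.11). Of 16 fatty acid synthesis genes, 9 rose and 1 fell, with Scd2 (5.32), Srebf1 (3.32), which encodes the lipogenic transcription factor SREBP1, and Acacb (3.31). Of 25 cholesterol synthesis and SREBP2 target genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with Insig1 (3.26) and Mvd (1.89). Of 24 fat absorption and chylomicron genes, 14 rose and 2 fell (14 and 3 adjusted over the list alone). Fabp1, a fatty acid binding protein, rose by 2.14 on the log2 scale, and Npc1l1, the cholesterol uptake transporter, fell by 2.16. The list tests gave adjusted p of 1.0e-11, 0.00016, 0.0010 and 0.0044, and adjusted p of 0.34, 0.47, 0.59 and 0.73 with an estimated correlation. Without genes held by more than 1 list, the fat absorption list gave an adjusted p of 0.12, and 8 of its 24 genes rose without control 482, knockout 476 or knockout 477. With library-size scaling alone, 19 oxidation genes rose and 3 fell, 6 fatty acid synthesis genes rose and 1 fell, 7 cholesterol genes rose and 4 fell, and 9 fat absorption genes rose and 5 fell. Of 7 ketogenesis genes 2 rose and none fell, and of 21 genes of fructolysis, glycolysis and gluconeogenesis 3 rose and 5 fell (2 fell without control 482, control 483 or knockout 477, and 3 without knockout 423). Pgk1 (1.32) rose and Mlxipl, the carbohydrate-response transcription factor ChREBP, fell by 1.59.

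Of 10 thyroid hormone targets, 7 fell, among them Dio1 (log2 fold change -3.46), Slc16a10 (-2.36) and the receptor gene Thrb (-2.22), and 2 rose, among them Me1 (2.89). Of 11 retinoid genes, 4 rose and 2 fell: Lrat (-5.63) and Bco1 (-5.66), which act in retinyl ester and carotenoid metabolism, fell, and Aldh1a1 (2.92) and Isx (1.51) rose. Of 10 FXR and bile acid genes 4 rose and none fell (4 and 1 adjusted over the list alone), with the FXR gene Nr1h4 (2.42) and its target Nr0b2 (5.01). Of 13 LXR targets, 6 rose and 3 fell (7 and 3 adjusted over the list alone), with Mylip (-3.30) and the receptor gene Nr1h3 (-1.87) among those that fell. Without knockout 476, 2 LXR targets rose and 2 fell, and with library-size scaling alone 2 rose and 3 fell; without knockout 477, 2 FXR genes rose. None of these 4 lists passed camera (adjusted p of 0.12, 0.88, 0.12 and 0.17). Of 30 nuclear receptor genes 4 rose and 10 fell (6 without control 483). Those that rose include Esr1, whose counts may hold reads of the Cre-ERT2 transgene. Of 6 vitamin D receptor targets and calcium absorption genes, 4 rose, with the calcium-binding protein gene S100g (6.96), Cldn2 (5.76) and Cyp3a11 (3.20); camera gave an adjusted p of 0.0049, and the adjusted p was 0.34 with an estimated correlation.

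Of 20 xenobiotic response genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with Gstm1 (log2 fold change 4.36) and Ces2a (3.50). Of 12 NRF2 antioxidant genes 10 rose and none fell, with Hmox1 (4.60), Gsta4 (4.53) and Gclc (3.12). Of 9 iron absorption genes 4 rose (5 adjusted over the list alone), including the ferritin gene Fth1 (3.40) and the exporter ferroportin (Slc40a1, 3.78). Of 21 unfolded protein and integrated stress response genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone), with Chac1 (5.51), Psat1 (3.10) and Asns (2.56). Camera gave adjusted p of 0.00025, 1.9e-06, 0.0094 and 0.0055 for these lists, and adjusted p of 0.38, 0.38, 0.34 and 0.64 with an estimated correlation. Without genes held by more than 1 list, the iron list gave an adjusted p of 0.070.

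Peptide digestion and amino acid transport genes fell: 16 of 23 tested fell and 1 rose (17 and 1 adjusted over the list alone). The aminopeptidases Xpnpep2 (log2 fold change -6.99) and Anpep (-2.77), the metalloprotease Mep1a (-5.19), the dipeptidyl peptidase Dpp4 (-3.17) and the amino acid transporter Slc43a2 (-4.14) were among them. Camera gave an adjusted p of 1.9e-06, and the adjusted p was 0.34 with an estimated correlation.

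Tuft cell markers fell furthest of the cell type lists: 17 of 19 tested fell and none rose, with a median log2 fold change of -4.99 (-4.74 with the 2 members without a count in any knockout library set at their bounds, against 3 counts over the group). Pou2f3, the transcription factor that specifies tuft cells, had 692 counts over the controls and 1 over the knockouts, 405-fold lower (95% counting interval 72.5 to 16027). Avil (-4.99), Lrmp (-3.81) and Alox5 (-5.56) fell as well. Of 13 Paneth cell markers 8 fell and none rose, with Ang4 (-6.60), Itln1 (-3.59) and Defa30 (-2.50), a family whose near-identical members share reads; 5 fell without control 486, without knockout 476 or without knockout 477. Camera gave adjusted p of 3.9e-08 for the tuft list and 0.016 for the Paneth list, and adjusted p of 0.48 and 0.73 with an estimated correlation; without control 486 the Paneth list gave 0.065. Of 17 goblet markers 3 rose and 6 fell (Agr2 1.63, Fer1l6 -1.69), and of 22 enteroendocrine markers 2 rose and 4 fell (Gip -2.78, Sst -1.35, Reg4 1.92). Of 14 stem cell markers 2 fell, including Axin2 (-1.95), of 28 proliferation genes 2 rose, including Pcna (1.87), against 1 adjusted over the list alone, and of 18 enterocyte markers 5 rose and 6 fell. Without knockout 423, 5 stem cell markers fell, and 1 proliferation gene rose and 3 fell. Of 9 proximal markers 3 rose and 3 fell, and of 10 distal markers 1 rose and 2 fell (2 and 5 adjusted over the list alone), with 4 that fell without control 483.

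MHC class II genes fell: 7 of 8 tested, with H2-DMb1 (log2 fold change -5.17), H2-DMa (-3.69) and the transactivator gene Ciita (-3.76). The class II beta chain gene H2-Ab1 stood at 125, 546 and 126 CPM in controls 482, 483 and 486 and at 20.6, 5.68 and 2.53 CPM in knockouts 423, 476 and 477. Only 3 of the 8 passed without control 482, where H2-Ab1 had an adjusted p of 0.055, and 4 without knockout 476. Camera gave an adjusted p of 0.0010, and the adjusted p was 0.64 with an estimated correlation. Of 24 interferon response genes 1 rose and 7 fell (1 and 10 adjusted over the list alone), with Oas2 (-3.64), and 4 fell without control 483 or knockout 423. Among leukocyte and stromal markers that scraped epithelium could hold, 1 of 16 genes on the T cell list fell (Ptprc, the general leukocyte gene CD45, -1.78). None of 8 B and plasma cell markers passed the test at a median of -1.65, and of 14 myeloid markers 2 rose and 2 fell. Of 15 mesenchyme markers 1 fell (0 adjusted over the list alone), of 7 endothelial markers 2 fell (3 adjusted over the list alone; 4 without knockout 423), of 2 enteric neuron markers none passed, and of 4 pancreatic acinar markers 1 rose (Cela1, 1.86). All 5 erythrocyte genes rose with the 6 libraries, at a median log2 fold change of 3.99. By edgeR 0 of 5 passed without control 482, 0 without control 483 and 1 without control 486, at medians of 3.68, 3.97 and 4.39, with 1, 5 and 4 at an unadjusted p under 0.05. Without knockout 477 the 5 passed at a median of 2.46. Hbb-bs stood at 80.0, 23.5 and 324 CPM in knockouts 423, 476 and 477 and at 4.81, 8.85 and 13.3 CPM in controls 482, 483 and 486. Its call (adjusted p = 0.017) was lost without control 482, 483 or 486 (adjusted p of 0.13, 0.079 and 0.069), and the erythrocyte list gave an adjusted p of 0.025 with camera and an adjusted p of 0.73 with an estimated correlation.

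**Figure D2:**
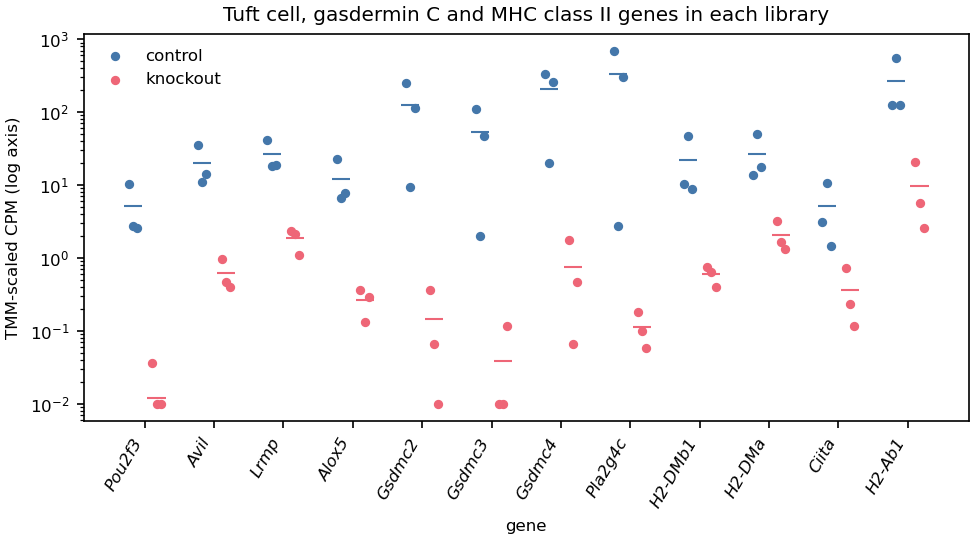
TMM-scaled CPM on a log axis for tuft cell genes, gasdermin C genes, Pla2g4c and MHC class II genes; points are libraries, short lines are group means, and libraries without a count are drawn at the bottom of the axis. In each of these genes the 3 knockout libraries lie below the 3 control libraries.

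For each list given with a single pair of counts, the counts adjusted over the list alone were the same. Of 13 regenerative and fetal-like genes 4 rose and 1 fell, with the growth factor genes Areg (log2 fold change 4.77) and Ereg (3.92); camera gave an adjusted p of 0.042, and the adjusted p was 0.38 with an estimated correlation. That call was lost without control 482 (0.053) or control 486 (0.065) and after the length and GC trend was removed (0.061). Of 19 clock genes 4 rose, among them Nfil3 (3.65) and Arntl (1.98), and 8 fell, among them Hlf (-6.42) and Dbp (-1.83); 4 fell without control 483, knockout 423 or knockout 477, and 5 without control 482. Of 13 Notch pathway genes 3 fell, including the ligand genes Dll4 (-2.65) and Dll1 (-1.76). Of 14 antimicrobial and stress genes 4 rose (Sprr2a1, 3.41, whose first exon overlaps that of a paralog) and 3 fell (Fut2, -5.23); adjusted over the list alone, 4 rose and 4 fell. Of 20 intestinal transcription factors 2 rose and 6 fell (Maf -2.96, Klf4 -1.24; 4 and 6 adjusted over the list alone), and 3 fell without knockout 477. Of 11 inflammatory genes 1 rose (Cxcl16, 2.73) and 2 fell (1 adjusted over the list alone), and of 13 p53 and apoptosis genes 5 rose (Bax, 1.04) and 1 fell (5 and 2 adjusted over the list alone). Of the p53 genes 2 rose without control 482, knockout 423 or knockout 477, 3 without control 483, and with library-size scaling alone 1 rose and 3 fell. Of 27 oxidative phosphorylation genes 2 rose (Ndufa4, 1.89; 1 adjusted over the list alone) and 2 fell (Ppargc1a, -1.65), whereas 11 rose without control 486. Other counts of 3 or fewer members rest on few genes, and several of them moved when a library was left out. Of 15 immediate-early genes 1 rose (Btg2, 1.74) and 3 fell (Fosb, -2.63), and of 4 sex-linked genes 1 rose and 1 fell (1 and 3 adjusted over the list alone). The 4 Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d had counts in each of the 6 libraries. The mean log2 CPM of the sex-linked list ran from 4.06 in knockout 423 to 4.89 in control 482.

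**Figure D3:**
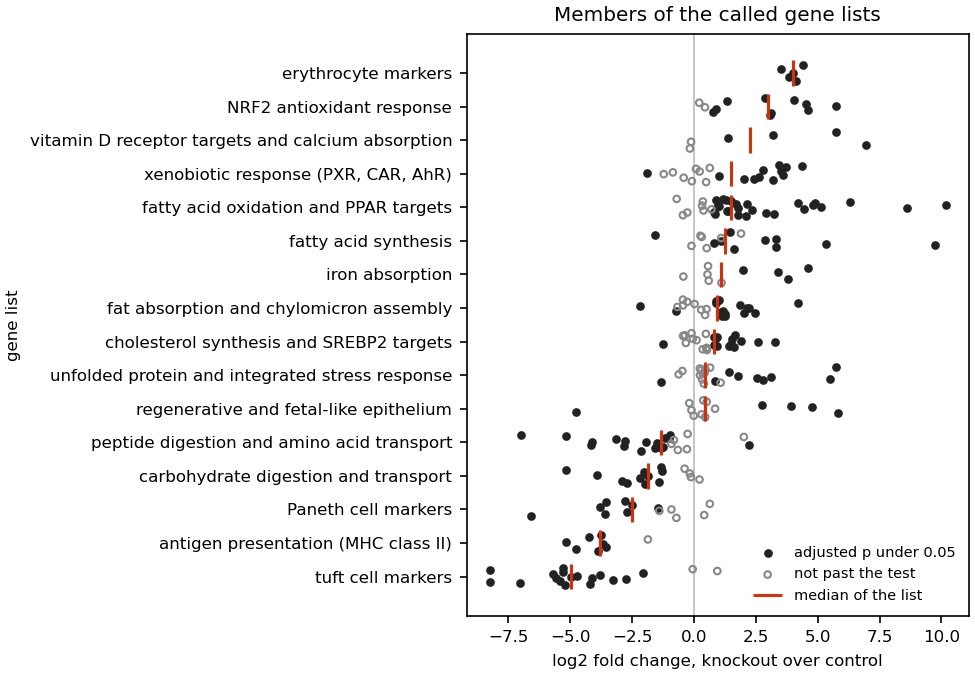
Log2 fold change, knockout over control, of each tested member of the 16 gene lists that camera called with its preset correlation; filled points passed an adjusted p of 0.05, open points did not, and the red line is the list's median. The medians run from -4.99 for tuft cell markers to 3.99 for erythrocyte markers.

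Camera with its preset correlation called 16 of 47 tested lists, 11 upward and 5 downward. With an estimated correlation it called none (5 at an unadjusted p under 0.05), whereas fry called 21. The loss of calls is not a measure of correlation alone. The vitamin D, iron and regenerative lists lost their calls at estimated correlations of -0.013, -0.0185 and -0.0046, below the preset 0.01. Regroupings of the same 6 libraries across genotypes gave up to 19 lists by camera at the preset correlation. By edgeR they gave no gene (94 to 1323 genes at an unadjusted p under 0.05). Each regrouping keeps part of the genotype difference, so these counts do not measure chance. The median, the mean and camera's direction differed in sign for retinoid, mesenchyme, proximal, antimicrobial, nuclear receptor and immediate-early genes, none of them called. Fold change also went with gene length, with a Spearman rho of -0.37 across genes, which are not independent replicates: the median log2 fold change was 0.96 in the shortest decile of genes (median exon length 459 bases) and -0.56 in the longest (11553 bases). After each library's trend with length and GC content was removed, 3957 of the 5348 changed genes (74.0%) passed again in the same direction, and the carbohydrate list had 11 of 15 members lower. Several uncalled lists moved with that correction: 2 retinoid genes were higher and 3 lower, 1 goblet marker was higher and 7 lower, 2 enteroendocrine markers were higher and 7 lower, 5 distal markers and 3 fructolysis and glycolysis genes were lower, and 4 intestinal transcription factors were higher and 5 lower. Among named genes that passed in both fits, the correction moved the log2 fold changes of short genes down, to 1.13 for Fabp1, 6.0 for S100g, 3.21 for Hbb-bs, 1.16 for Reg4, 1.28 for Ndufa4, -3.64 for Defa30, -7.51 for Ang4, -3.56 for Gip, -4.20 for Itln1 and -1.96 for Sst, and that of the long Acacb up to 3.92. With library-size scaling alone, uncalled lists had more members that fell, among them 14 of 24 interferon, 9 of 21 fructolysis and glycolysis, 8 of 22 enteroendocrine, 6 of 13 Notch, 5 of 10 distal, 5 of 15 immediate-early, 4 of 11 retinoid and 4 of 27 oxidative phosphorylation genes. So did 15 of 30 nuclear receptor, 11 of 19 clock and 9 of 18 enterocyte genes. The same held for 9 of 20 intestinal transcription factors and 8 of 15 corepressor complex members. In the called stress response list 6 rose and 3 fell under that scaling.

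**Figure D4:**
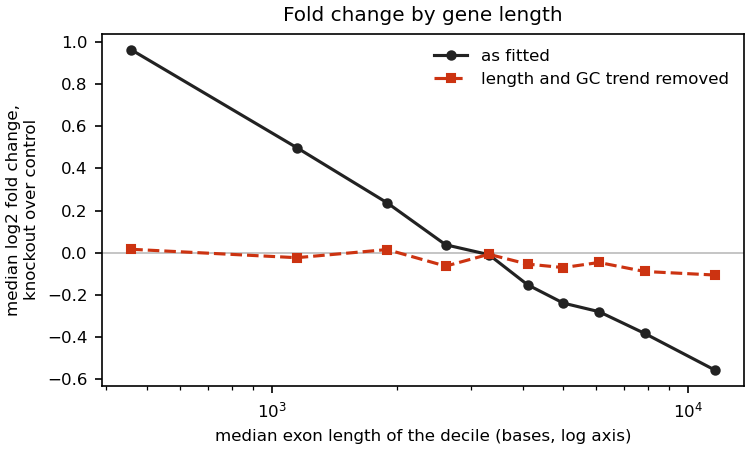
Median log2 fold change, knockout over control, in deciles of the genes by exon length (bases, log axis), as fitted and after the length and GC trend of each library was removed. The fitted medians run from 0.96 in the shortest decile to -0.56 in the longest, and the corrected ones from 0.0167 to -0.11.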

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

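The removal of the trend with length and GC, or with length alone, was chosen after the data were seen; all other alternatives were set before the data were examined. Ncor1 was lower and past the threshold under every alternative run on single genes (all but the 1.5-fold test). Of 5348 changed genes, a test against a 1.5-fold change left 2632 (1221 higher, 1411 lower; fewer by its construction), and leaving out each library gave 3299 (without control 482) to 5940 (without control 486) changed, 1510 to 2958 higher and 1748 to 2982 lower; 3545 passed without control 483 and 3396 without knockout 477. With library-size scaling alone the median of all genes moved by -0.44 and the split became 1133 higher and 4554 lower (19.9% higher against 48.5%); the other counts stayed within 1.5 times. DESeq2 called 5976 genes, and without a filter 6280 of 27205 passed.

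None of the 16 called lists (0) passed with an estimated correlation: adjusted p was 0.34 for carbohydrate, fatty acid oxidation, vitamin D, peptide digestion and iron genes, 0.38 for xenobiotic, NRF2 and regenerative genes, 0.47 for fatty acid synthesis, 0.48 for tuft, 0.59 for cholesterol synthesis, 0.64 for MHC class II (0.644) and stress response (0.637), and 0.73 for fat absorption, Paneth and erythrocyte lists. The estimated correlations of the vitamin D (-0.013), iron (-0.0185) and regenerative (-0.0046) lists lay below the preset 0.01. For these lists a higher correlation does not account for the loss. With fry, which tests another hypothesis, Paneth (0.12) and erythrocyte (0.11) lists were lost and ketogenesis (0.0019), LXR (0.010), FXR (0.0065), thyroid (0.0028), pancreatic (0.021), antimicrobial (0.045) and p53 (0.041) lists passed; uncalled lists changed direction there for retinoid (0.45), proximal (0.50) and nuclear receptor (0.89) genes. Without genes of more than 1 list, fat absorption (0.12) and iron (0.070) were lost and retinoid genes changed direction (0.90). The regenerative list was lost with ranks (0.10) and with the length and GC trend removed (0.061).

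Each library left out in turn gave these adjusted p, lowest to highest: Paneth 7.4e-06 to 0.065 (without control 486), regenerative 0.023 to 0.065 (without control 486; 0.053 without control 482), stem cell 0.0037 (without knockout 423) to 0.33, B cell 0.025 (without knockout 423; 0.029 without control 482) to 0.32, interferon 0.016 (without control 482) to 0.50 and oxidative phosphorylation 0.011 (without control 486) to 0.38. Uncalled lists that changed direction were retinoid (0.68 to 0.94; without control 482), enterocyte (0.31 to 0.91; without knockout 423), proliferation (0.051 to 0.77; without knockout 423), T cell (0.032 without control 482, to 0.96; without control 483 or knockout 423) and proximal (0.72 to 0.94; without control 486 or knockout 423).

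Of single genes, Sis was 0.17 with length alone removed, Slc2a1 -0.18 with library-size scaling and -0.13 without knockout 423, and Slc5a4b 0.0081 without knockout 423 (-0.28 without control 482), none past the threshold. Pla2g4c was lost with limma-voom (adjusted p = 0.11, or 0.20 with sample weights) and Gsdmc3 with sample weights (0.060). Why these values moved between settings was not tested. At this depth 3 counts, the limit that a count of 0 allows, stand for 0.0586 to 0.173 CPM in a library.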

Other observations

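The tests of symbol families, of a type 2 response and crypt cells for the tuft markers, and of B cells and leukocytes for the MHC class II genes were chosen after the values were seen, as was the length and GC correction. Among 208 symbol families of 8 or more tested genes, each tested for an excess of higher and of lower genes (Fisher's exact test, one-sided, Benjamini-Hochberg over both), ribosomal protein, mitochondrial ribosome and proteasome families had an excess of higher genes. These tests treat genes as independent, so their p-values do not measure the spread between mice. Of 123 Rpl genes 86 rose (adjusted p = 1.5e-35) and of 93 Rps genes 67 rose and 3 fell (adjusted p = 5.7e-29), but these stems hold processed pseudogenes that share reads. After the length and GC trend was removed 40 and 26 were higher (adjusted p of 4.0e-05 and 0.021 by the same test). Of 14 Psmd genes 10 rose and none fell (adjusted p = 0.0007), and of 11 Psmb genes 8 rose and 1 fell (adjusted p = 0.0033). Of 50 Mrpl genes 35 rose and none fell, and of 31 Mrps genes 15 rose and none fell. The mitochondrial import family Timm (8 of 14), the COP9 signalosome family Cops (7 of 9) and the translation initiation family Eif (24 of 62, with 2 lower and the rest not past the test) had an excess of higher genes as well. All 8 glutathione transferases of the Gstm family rose, at a median log2 fold change of 3.46. Whether these related genes share reads was not tested, so they may not be separate rises. Of 48 Cyp genes 22 rose and 11 fell (adjusted p = 0.00034).

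Of 251 Slc genes, a stem of many unrelated carriers, 74 fell and 42 rose (adjusted p = 0.00066 for lower), and 68 were lower after the correction (0.0026). The families Arhgef (11 of 19), Kdm (10 of 17), Adcy (6 of 8) and Pik (8 of 14) had an excess of lower genes, and Acot (7 of 12) and Chchd (6 of 9) of higher genes, at adjusted p of 0.0047, 0.0074, 0.022, 0.034, 0.037 and 0.034, but these did not pass after the correction (0.63, 0.80, 0.35, 0.10, 0.10 and 0.10). The Defa family passed only after it, with 8 of 14 lower (0.028). After the length and GC trend was removed, 11 of 14 Psmd, 8 of 11 Psmb, 29 of 50 Mrpl, 14 of 31 Mrps and 8 of 8 Gstm genes were higher. With library-size scaling alone, which moves the median of all genes by -0.44, none of the families named here changed the sign of its median, but 31 of 123 Rpl, 25 of 93 Rps, 4 of 14 Psmd, 12 of 50 Mrpl, 10 of 31 Mrps, 4 of 14 Timm, 2 of 9 Cops and 3 of 9 Chchd genes passed as higher. The Psmb family then had 8 higher and 3 lower of 11, the Eif family 7 higher and 7 lower of 62, the Cyp family 19 higher and 17 lower of 48, the Slc family 25 higher and 108 lower of 251, and the Gstm family 8 of 8 higher.

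With 10 splits of 6 libraries a share of splits under 0.05 cannot be reached: the real split gave 5348 genes, the highest other 0 (94 to 1323 genes at an unadjusted p under 0.05 by edgeR), and 1 of 10 splits gave as many. Of the gene lists the real split gave 16, the highest other 19, and 5 of 10 splits, the real one included, gave as many. Camera at its preset correlation thus also called lists in groupings that mix the genotypes. Every other split mixes them unevenly, so part of the genotype difference stays between the groups and the rest adds to the spread within them. The gene and list counts of the other splits are therefore not counts under no difference.

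Longer genes were lower in the knockout libraries, but 74.0% of the genes called passed again in the same direction after the length and GC correction, which argues against the trend as the whole cause of the calls. Families of mostly short genes (ribosomal proteins, mitochondrial ribosome, proteasome, respiratory chain and similar) were tested as the cause. They held 535 of the 15028 genes tested, so leaving them out could change the Spearman rho little. Outside them rho was -0.35, so the trend was not confined to these families. The slope of relative log2 CPM on log2 length was 0.25, 0.19 and 0.0036 in controls 482, 483 and 486 and -0.17, -0.066 and -0.21 in knockouts 423, 476 and 477. The largest span within a genotype was 0.84 of the difference between the genotype means, so RNA integrity or library preparation may contribute to the trend. An effect of the genotype on long genes stays open, since every knockout slope lies below every control slope.

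Tuft cell markers were lower in the knockouts. The length trend was tested first: the median log2 fold change was -4.87 after the length and GC correction, which argues against it. Fewer crypt cells in the scrapings would lower stem cell and proliferation genes as well; the lower of those medians was -0.53 (-1.06 for stem cell and -0.60 for proliferation genes without knockout 423, against -5.91 for the tuft markers), which argues against that as the whole cause, although Paneth markers, also of the crypt, fell. A type 2 response, which expands tuft cells, in controls 482 and 486 may contribute, because their gasdermin C genes stood above those of control 483. The mean log2 CPM of the tuft markers was 3.72, 2.43 and 2.64 in controls 482, 483 and 486, so control 486 lay close to control 483. In control 483 the median marker still lay 3.72 log2 units above the knockout mean, but 1 library cannot decide whether such a response contributes. Whether fewer tuft cells or lower expression per cell underlies the fall was not tested.

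MHC class II genes were lower in the knockouts. B cells in control 483, where these genes stood highest, were tested as the cause: without that library the median log2 fold change was -2.76 and 5 of 8 genes passed, which argues against them as the whole cause. An even loss of leukocytes would lower B cell, T cell and myeloid markers alike. Relative to those lists the mean of the class II genes changed by -2.12 (B cell), -3.76 (T cell) and -3.41 (myeloid) log2 units. The genotypes did not overlap, which argues against an even loss as the whole cause. A loss of only the leukocytes that carry class II would not lower all of these lists, so the comparison cannot decide on it. The mean log2 CPM of the B cell list was 2.39, 4.66 and 3.42 in controls 482, 483 and 486. In knockouts 423, 476 and 477 it was 3.38, 1.88 and -0.0446. After the length and GC correction the median was -3.90. Which cells account for the fall, and any difference in the mice's microbiota or inflammation, was not tested.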
